A study of Mus musculus with 9 samples.

How the data were processed

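Total RNA from primary newborn mouse calvarial osteoblasts carrying a doxycycline-inducible RUNX2 lentivirus was measured on 9 Illumina mouse bead arrays. Per the labels' protocols, RNA was extracted with Trizol and cleaned with an RNeasy kit and DNase, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. Samples were grouped by their titles in the labels into vehicle (n = 2), dox (n = 2), E2 (n = 3) and dox plus E2 (n = 2). Replicates of dox plus E2 are numbered 2 and 3 in the labels. The sample descriptions in the labels place vehicle and dox arrays on slide 1 and E2 and dox plus E2 arrays on slide 2, and on both slides the arrays without dox hold positions A to C and those with dox positions E to G.

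The deposited table holds, per the file headers, an average bead signal and a detection p-value for each of 25697 probes per array. The signal is a linear intensity without background subtraction or scaling between arrays, as the deposited values show, and it was made with GenomeStudio 2011.1 per the submitters' processing notes. The deposited detection p-values move in steps of 1 in 798, as a rank against negative control probes would. Lowest signals per array ran from 80.6 to 103, and median signals were 149.9, 139.8, 132.2 and 131.8 on slide 1 and from 157.9 to 172.1 on slide 2. A second deposited table holds intensity values scaled by the authors; a quantile normalization of the signals gave the same values within 0.515%, on a linear scale and with no centring per gene, and its array medians were 152.7 to 153.0. The genome build used for the probes is not given in the sources used here. Gene symbols came from the table and were updated with the RefSeq gene table of the mouse assembly GRCm38.p6, used only for names and chromosomes: 20733 probes had a current symbol, 3872 were renamed through a synonym, 3 by hand and 1089 kept the symbol of the table.

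Signals were background-corrected by the normexp method with parameters taken from the detection p-values, quantile normalized and put on the log2 scale with an offset of 16 (neqc of limma 3.58.1 in R 4.3.3). Quantile normalization gives each array the same distribution, so a change of most genes in 1 direction would not be seen, and the offset shrinks changes of dim probes toward 0. Probes with a detection p under 0.05 on at least 2 arrays were kept (12912), and a gene was represented by its probe with the highest mean (9490 genes; 7042 had 1 kept probe and 2448 several). Where all arrays of a group were below background for the probe, the fold is given as a bound.

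All 9 arrays were fitted together in limma with a mean per group, so that groups of 2 and 3 share an estimate of the spread, and with an intensity trend in the variance prior. Tests were two-sided moderated tests with Benjamini-Hochberg adjustment over all genes, and a gene passed at an adjusted p under 0.05. The comparisons were dox against vehicle, dox plus E2 against E2, the difference of these dox effects, E2 against vehicle, dox plus E2 against dox, and the 4 dox arrays against the 5 others with slide as a block. A slide effect that adds the same amount to all arrays of a slide drops out of the dox comparisons and of the difference. A dox effect that itself differs between slides does not drop out of the difference and cannot be told apart from E2. The size of the dox response with and without E2 was compared over the genes that passed in the last comparison, with fry. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 18 lists and 5 comparisons (90 tests). Of these, 11 list shifts passed, and 0 did with an estimated correlation. That alternative changes more than the correlation. For dox against vehicle the osteoblast list had an estimated correlation of -0.018, under the preset 0.01, yet its unadjusted camera p rose from 0.00286 to 0.0237. Intervals are at 95%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

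The groups, comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. Genes always named were Runx2, Tnfsf11, Tnfrsf11b, Csf1, Esr1, Pgr, Greb1, Bglap, Spp1, Ibsp, Alpl and Mmp13. Per comparison, among genes past the threshold whose arrays did not overlap between the groups, the 10 with the largest rise and the 10 with the largest fall were named (5 and 5 for the E2 comparisons and for dox against no-dox arrays), with no condition on overlap for the difference and for dox against no-dox arrays. Up to 4 members of each list with the smallest p among those past the threshold were added. The lists covered osteoblast matrix and mineralisation, reported RUNX2 targets, osteoclast-regulating factors, RANKL shedding and vesicle sorting, oestrogen response, cell cycle, integrated stress response, inflammatory cytokines and NF-kB, interferon response, Wnt and BMP or TGF-beta pathways, collagens, matrix proteases, and markers of chondrocytes, adipocytes, macrophages and osteoclasts, endothelium and muscle. After the values were seen, lists of heart muscle, fast skeletal muscle and immediate early genes were written for the closing observations, with the genes that had prompted them kept apart.

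The code was tested on simulated arrays of 9490 genes with 50 changed by each of 0.5, 1, 1.5 and 2 on the log2 scale. Noise was drawn independently per gene and array. Where fewer genes change, the adjusted threshold is stricter, so these rates may exceed those in the real data. Of genes changed by 1 on the log2 scale it recovered 92% for dox against vehicle and for dox plus E2 against E2, 66% for the difference, 88% for E2 against vehicle and 100% for dox against no-dox arrays. Of those changed by 0.5 it recovered 60%, 56%, 36%, 54% and 70%. False calls were 9 of 184, 12 of 186, 9 of 159, 7 of 178 and 9 of 194. Simulated lists of 20 genes shifted by 0.3 were found in 100% of 50 simulations, and 3.6% of unshifted lists were called, at an unadjusted p under 0.05.

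Alternatives were no background correction, median scaling, the authors' scaled values, no filter or a stricter filter on detection (p under 0.01 on every array of a group), the mean of a gene's probes, no intensity trend, only the arrays compared, array weights, a replicate block, normalization within each slide, no slide term, an estimated correlation for lists, and leaving out each array in turn. No pair of arrays held identical values (0), and 0 columns belonged to other samples. Correlations between arrays of a group were 0.9921 to 0.9946, between groups of a slide 0.9919 to 0.9936, and between slides 0.9894 to 0.9926. No array was left out of the main results.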

Results

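Messenger RNA levels were measured on 9 Illumina mouse bead arrays in primary osteoblasts from newborn mouse calvaria, the bones of the skull roof. All cells carried a lentivirus that expresses RUNX2, a transcription factor of bone formation, under control of doxycycline (dox). The cells were kept in medium with charcoal-stripped serum, which is low in steroid hormones, and were treated for 48 h. The groups were vehicle (n = 2), dox at 500 ng/ml (n = 2), oestradiol (E2) at 10 nM (n = 3) and dox plus E2 (n = 2). Vehicle and dox arrays lay on slide 1, and E2 and dox plus E2 arrays lay on slide 2, so the dox comparisons lie within a slide while slide and E2 cannot be told apart. Between 11554 and 12206 of 25697 probes per array were above background, and 9490 genes were tested. Nothing in the labels says that replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. The small number of arrays limits the precision of each value. Changes are log2 differences ± standard error (SE) from limma with Benjamini-Hochberg adjusted p-values, unless stated otherwise.

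The RUNX2 transcript itself could not be read on these arrays. Both probes of Runx2 (ILMN_1220130 and ILMN_2599072) were below background on 9 of 9 arrays, with lowest detection p-values of 0.294 and 0.368, in dox arrays as in the others. Where these probes lie relative to the sequence carried by the virus is not given in the sources used here, so they do not test whether the transgene was on. The oestrogen receptor gene Esr1 and the oestrogen-responsive genes Pgr and Greb1 were likewise below background on all 9 arrays, as was Ibsp, which codes for bone sialoprotein.

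Dox against vehicle asked which genes change when RUNX2 is switched on without E2. Gzmd (ILMN_2987649, chromosome 14), a granzyme serine protease best known from cytotoxic lymphocytes, rose 3.01-fold with dox (log2 change 1.59 ± 0.16, n = 2 and 2, adjusted p = 7.61e-06). Dapk2 (ILMN_2977558, chromosome 9), a calmodulin-regulated kinase, rose 2.62-fold (1.39 ± 0.19, adjusted p = 0.000988). Pacsin1 (ILMN_2644415, chromosome 17), an adaptor protein of membrane trafficking, rose at least 2.31-fold (adjusted p = 0.00116), from a probe below background on both vehicle arrays. Here and below, a bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes above background and the dim probe's own signal. These were the 3 genes past the threshold, and the arrays of the groups did not overlap for 3 of 3. Chance alone gives this separation, in either direction, for 33.3% of unselected genes. Genes chosen by a test on the same arrays are mostly separated anyway, so it adds no support. At an unadjusted p under 0.05 there were 642 genes.

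The osteoblast markers did not pass the threshold one by one in this comparison. Sp7, the osteoblast transcription factor osterix, had a log2 change of 0.64 ± 0.12 (adjusted p = 0.0569). The osteocalcin gene Bglap2 had 1.27 ± 0.26 (adjusted p = 0.117) and Alpl, the alkaline phosphatase of mineralising cells, 0.68 ± 0.19 (adjusted p = 0.464). Spp1, which codes for osteopontin, had 0.12 ± 0.09 (adjusted p = 0.828), and the collagenase gene Mmp13 0.05 ± 0.13 (adjusted p = 0.963). As a group, the reported RUNX2 target genes shifted up (camera adjusted p = 3.94e-05): 12 of 13 tested members had positive values with a median of 0.12, 0 passed over all genes, and 4 passed when adjusted over the list alone. With an estimated correlation between genes this shift had an adjusted p = 0.244. The mean over the list was 0.33, above the median, with its members Bglap2, Bglap (0.91 ± 0.31, adjusted p = 0.633), Alpl and Sp7 at 0.64 or more. Bglap and Bglap2 count as separate members, though a probe may read both. The osteoblast matrix and mineralisation list, which holds these genes too, shifted up as well (11 of 17 positive, median 0.12, camera adjusted p = 0.0282, and adjusted p = 0.484 with an estimated correlation). Of its members 0 passed over all genes and 5 when adjusted over the list alone. Cell cycle genes shifted down (19 of 24 negative, median -0.12, camera adjusted p = 0.0282, and adjusted p = 0.611 with an estimated correlation), with Bub1b at -0.57 ± 0.20 and Kif11 at -0.40 ± 0.20, and 0 passed over all genes or when adjusted over the list alone.

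Dox replicate 2 stood apart from dox replicate 1 in immediate early genes, a class chosen after the values were seen. Its Fos level was 7.52 on the log2 scale against 10.41 in dox replicate 1 and 10.06 and 10.23 in the vehicle arrays, and its Egr1 level was 12.23 against 13.78, 13.71 and 13.88. Without dox replicate 1, 11 genes passed, with Fos (-2.63 ± 0.18), Egr1 (-1.57 ± 0.10), Zfp36 (-1.35 ± 0.14), Junb (-0.73 ± 0.14), Hmga1 and Tbc1d2b as the 6 that fell. Without vehicle replicate 1 or without dox replicate 2 only Gzmd passed (1 gene each), with Pacsin1 at adjusted p = 0.0531 and 0.0592 and Dapk2 at 0.0872 and 0.0558, and 5 genes passed without E2 replicate 1. Dapk2 also lost its call without the intensity trend. The osteoblast list lost its call without vehicle replicate 1 (adjusted p = 0.0894), dox replicate 2 (0.218) or dox plus E2 replicate 2 (0.0981), and the cell cycle list without vehicle replicate 2 (0.154) or dox replicate 2 (0.334).

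The same treatment in the presence of E2, dox plus E2 against E2, raised 7 genes and lowered 0, with 591 genes at an unadjusted p under 0.05. Gzmd rose 3.53-fold (1.82 ± 0.15, n = 2 and 3, adjusted p = 8e-08) and the closely related Gzme (ILMN_2642942) 2.40-fold (1.26 ± 0.21, adjusted p = 0.00694). The osteoblast genes Alpl (ILMN_2661287, chromosome 4; 1.99-fold, 0.99 ± 0.17, adjusted p = 0.0089) and Sp7 (ILMN_2733114, chromosome 15; 1.64-fold, 0.72 ± 0.11, adjusted p = 0.00393) rose. Bglap2 (ILMN_2944508, chromosome 3) rose at least 1.98-fold from below background (adjusted p = 0.00449), and Pacsin1 at least 2.17-fold (adjusted p = 0.000138). Dapk2 rose 2.00-fold (1.00 ± 0.18, adjusted p = 0.011). The arrays of the groups did not overlap for 7 of 7 genes, which adds no support, since the genes were chosen on the same arrays. Chance alone gives this separation for 20% of unselected genes.

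All 3 genes raised by dox without E2 were among these 7 (0.00221 expected for independent lists, one-sided exact hypergeometric p = 2.46e-10). Both comparisons use the same spread estimate per gene, so the lists are not independent, as that test assumes. Reported RUNX2 target genes shifted up again (10 of 13 positive, median 0.32, camera adjusted p = 3.65e-07, and adjusted p = 0.225 with an estimated correlation), with 3 higher over all genes (Alpl, Bglap2, Sp7) and 6 when adjusted over the list alone. The osteoblast list shifted up as well (10 of 17 positive, median 0.08, camera adjusted p = 0.00557, and adjusted p = 0.326 with an estimated correlation), with the same 3 members higher and 4 when adjusted over the list alone. Mmp13 was at 0.47 ± 0.12 (adjusted p = 0.341) and Spp1 at -0.09 ± 0.08 (adjusted p = 0.909). Cell cycle genes went both ways (12 positive and 12 negative, adjusted p = 0.824). Gzmd and Pacsin1 kept their calls with any array left out, while the other 5 genes lost theirs without either dox plus E2 array: 3 genes passed without replicate 2 (adjusted p of the 5 from 0.114 to 0.719) and 2 without replicate 3 (0.0983 to 0.341). Alpl (0.0868) and Dapk2 (0.0547) also missed the threshold without E2 replicate 2, Gzme (0.0667) and Dapk2 (0.0692) without E2 replicate 3, and the osteoblast list (0.2) without dox plus E2 replicate 2. Alpl, Gzme and Dapk2 also missed it with no detection filter (adjusted p 0.0837, 0.137 and 0.151; 4 of the 7 genes were kept) and with the replicate block (0.0598, 0.0638 and 0.0745), and these 3 and Sp7 without the intensity trend (0.177 to 0.341).

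**Figure D1:**
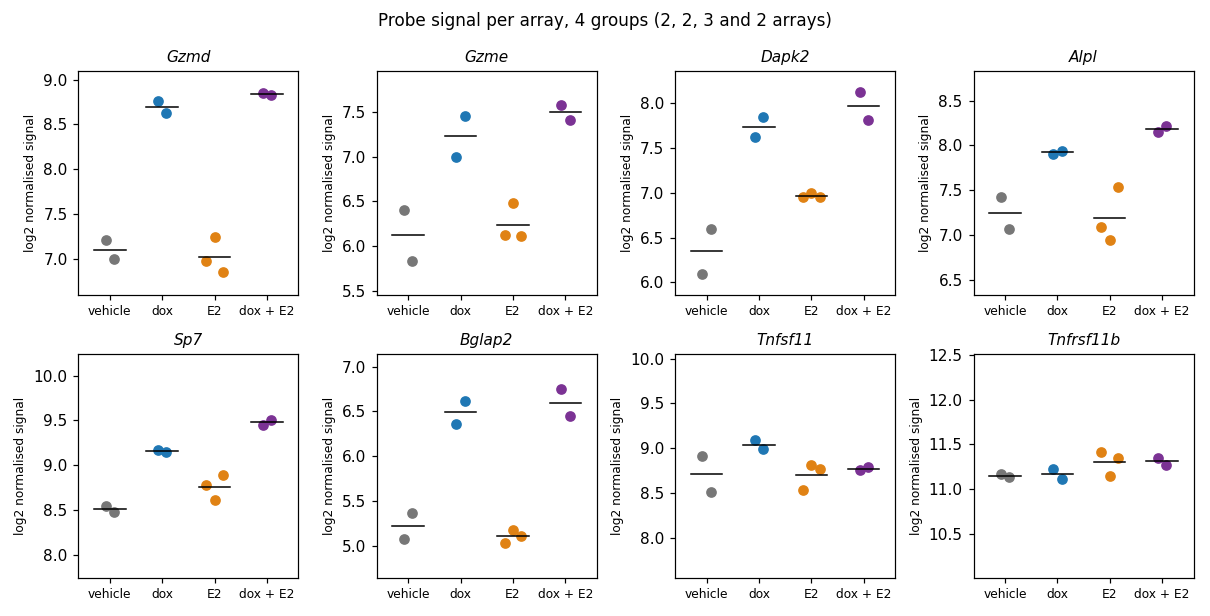
Normalised log2 intensity of 8 genes on each of the 9 arrays (dots) with the group mean (bar), by group. Gzmd averaged 7.10 with vehicle, 8.69 with dox, 7.02 with E2 and 8.84 with dox plus E2, while Tnfrsf11b averaged 11.15, 11.17, 11.30 and 11.31.

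Comparing all 4 dox arrays with all 5 arrays without dox, with the slide as a block, gave the dox response on the most arrays: 10 genes rose and 1 fell (555 at an unadjusted p under 0.05). Gzmd (1.72 ± 0.11, adjusted p = 1.42e-10), Dapk2 (1.18 ± 0.14, adjusted p = 1.03e-05), Sp7 (0.68 ± 0.08, adjusted p = 2.64e-05), Gzme (1.19 ± 0.15, adjusted p = 5.49e-05) and Alpl (0.85 ± 0.13, adjusted p = 0.000727) rose. Pacsin1 rose at least 2.25-fold (adjusted p = 2.22e-07) and Bglap2 at least 1.85-fold (adjusted p = 3.78e-05). Rgcc, a regulator of the cell cycle (0.58 ± 0.10), Serping1, the inhibitor of complement C1 (0.54 ± 0.11), and Olfml3, a secreted matrix protein (0.39 ± 0.08), rose as well and are named after their values were seen. Invs, which codes for the ciliary protein inversin, fell at least 1.36-fold (adjusted p = 0.0358). The osteocalcin gene Bglap was at 0.97 ± 0.21 (adjusted p = 0.0595). Without vehicle replicate 2 or dox plus E2 replicate 3, 7 genes passed, and Invs missed the threshold without either vehicle array, either dox array, E2 replicate 2 or 3, or dox plus E2 replicate 3 (adjusted p 0.0698 to 0.327). Invs also missed it without the intensity trend, with the replicate block and with no slide term, and Alpl without the trend. Rgcc, Serping1 and Olfml3 lost their calls without vehicle replicate 2, without dox plus E2 replicate 3, with the replicate block and without the trend.

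Probes of closely related genes limit what these names say. Gzmd and Gzme have near-identical sequences, and so do Bglap, Bglap2 and Bglap3, and the sources used here do not give the probe sequences, so a probe may read more than 1 of them. A weaker Gzmd probe had 0.58 without E2 and 0.57 with E2, while the probes of Gzmb, Gzmc, Gzmf, Gzmg and Gzmk were below background on all 9 arrays. Gzmn, above background on 2 arrays, had -0.21 without E2 and -0.33 with E2, and Gzmm, above background on 1 array, had 0.12 and -0.39. Of the other Pacsin1 probes, one was below background on all 9 arrays, and one, above background on 2 arrays, had -0.19 without E2 and 0.14 with E2. With the mean of a gene's probes in place of the brightest, Pacsin1 lost its call without E2 (adjusted p = 0.631) and with E2 (adjusted p = 0.237), and Gzmd without E2 (adjusted p = 0.0537).

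The difference of the dox effects, with E2 minus without, addresses the question in the series title, whether oestrogens alter what RUNX2 does in osteoblasts to drive osteoclast formation. Tnfsf11 (ILMN_2505780), which codes for the osteoclast-inducing ligand RANKL, had a dox effect of 0.33 ± 0.14 without E2 (adjusted p = 0.679) and of 0.06 ± 0.13 with E2 (adjusted p = 0.971). The difference was -0.27 ± 0.19 (95% interval -0.66 to 0.13, adjusted p = 0.825). Its group means were 8.71 ± 0.29 (SD) with vehicle, 9.04 ± 0.08 with dox, 8.71 ± 0.15 with E2 and 8.77 ± 0.02 with dox plus E2. Tnfrsf11b (ILMN_2513826), the gene of the RANKL decoy osteoprotegerin, had dox effects of 0.01 ± 0.09 and 0.01 ± 0.08 and a difference of -0.01 (95% interval -0.26 to 0.25). Csf1, the macrophage colony-stimulating factor, had a difference of -0.03 ± 0.11. The 16 tested osteoclast-regulating factors had 10 negative differences with a median of -0.06 (camera adjusted p = 0.533), and 0 passed over all genes or when adjusted over the list alone.

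No gene passed the threshold for a difference (0 of 9490 with limma, lowest adjusted p = 0.531), and 652 had an unadjusted p under 0.05. Alpl differed by 0.32 ± 0.26 (adjusted p = 0.855), Mmp13 by 0.42 ± 0.17 (adjusted p = 0.68) and Spp1 by -0.21 ± 0.12 (adjusted p = 0.773). In simulated data of this size the test recovered 66% of genes that differed by 1 on the log2 scale and 36% of those that differed by 0.5, so smaller differences were mostly not detectable. The simulation changed many genes and drew noise independently, which eases the adjusted threshold. With few genes that differ, recovery in the real data may be lower, also for differences of 1. For the 11 genes of the dox response the median change, turned by its sign, was 1.10 without E2 and 0.99 with E2, 7 of 11 were larger with E2, and the shift of the set did not pass (limma fry, adjusted p = 0.685 with 1 set tested, median difference 0.08). Across all 9490 genes, which are not independent replicates, the dox effects with and without E2 had Pearson's r = 0.049 and Spearman's rho = 0.001, against 60 relabellings within slides (exact two-sided p = 0.567 and 1). Of the 18 lists 1 passed for the difference: genes of inflammatory cytokines and NF-kB signalling had a higher dox effect with E2 (8 of 9 positive, median 0.28, camera adjusted p = 0.048, and adjusted p = 0.529 with an estimated correlation). The largest among them were C3 at 0.66 ± 0.39 and the transcription factor Irf1 at 0.55 ± 0.19, and 0 passed over all genes or when adjusted over the list alone. That call was lost without any of 7 arrays in turn: either vehicle array (adjusted p = 0.115 and 0.0514), either dox array (0.0857 and 0.13), E2 replicate 2 (0.0753) or 3 (0.0735), or dox plus E2 replicate 3 (0.247). Without dox replicate 1, where dox is represented by replicate 2 alone, 4 genes differed: Fos (2.76 ± 0.22), Egr1 (1.54 ± 0.12), Zfp36 (1.53 ± 0.17) and Ier3 (0.67 ± 0.13).

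**Figure D2:**
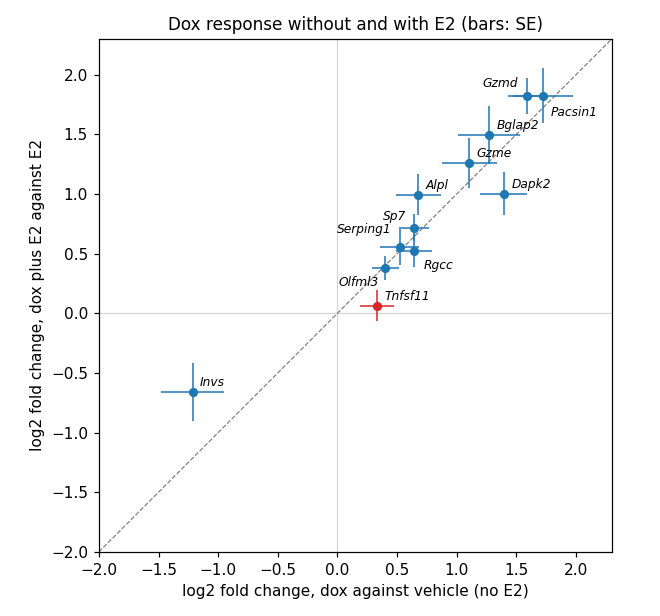
Log2 change with dox in the absence of E2 (horizontal axis) against that in its presence (vertical axis) for the 11 genes of the dox response and Tnfsf11 (red), with bars of 1 SE and a dashed line where both are equal. Gzmd lies at 1.59 and 1.82, Alpl at 0.68 and 0.99 and Tnfsf11 at 0.33 and 0.06.

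E2 against vehicle asked what E2 does without dox, but its arrays lay on different slides, so every value in this paragraph and the next is of slide and E2 together. The 5 genes with the largest fall belong to 2 classes that were chosen after these values were seen. Those of heart and slow muscle were Myl2, the ventricular myosin regulatory light chain (6.98-fold lower, fell by 2.80 ± 0.26 on the log2 scale, n = 3 and 2, adjusted p = 6.63e-07), cardiac actin Actc1 (5.17-fold lower, fell by 2.37 ± 0.24, adjusted p = 1.36e-06) and the myosin light chain Myl3 (4.65-fold lower, fell by 2.22 ± 0.25, adjusted p = 6.26e-06). The immediate early genes were Fos (7.76-fold lower, fell by 2.96 ± 0.40, adjusted p = 0.000123) and Egr2 (5.44-fold lower, fell by 2.44 ± 0.24, adjusted p = 1.3e-06). Beyond the genes that prompted these classes, 3 of 13 tested heart muscle genes fell and 0 rose, and of 18 tested immediate early genes 5 fell and 1 rose. The genes with the largest rise were the histone H3 gene H3c7 (at least 1.41-fold, adjusted p = 0.0393), the deubiquitinase gene Mindy3 (at least 1.38-fold, adjusted p = 0.0471), Mbip (0.87 ± 0.22), the Ras exchange factor Rasgrp3 (0.83 ± 0.21) and Phf23 (0.77 ± 0.19). In all 59 genes were higher and 79 lower, with 1484 at an unadjusted p under 0.05. The groups did not overlap for 138 of 138, which adds no support, since the genes were chosen on the same arrays. Chance alone gives this separation for 20% of unselected genes.

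Cell cycle genes shifted down between these groups, though not past the threshold in dox plus E2 against dox. Between E2 and vehicle, 21 of 24 were negative (median -0.22, camera adjusted p = 0.00334, and adjusted p = 0.484 with an estimated correlation). The mitotic kinesin Kif11 (-0.72 ± 0.19, adjusted p = 0.047) and Cdc20, an activator of the anaphase-promoting complex (-0.37 ± 0.09, adjusted p = 0.0399), fell, and 4 members passed when adjusted over the list alone. Collagen and matrix assembly genes shifted down (12 of 19 negative, median -0.12, camera adjusted p = 0.0282, and adjusted p = 0.611 with an estimated correlation), with 0 past over all genes, 7 when adjusted over the list alone, and for example Fbln1 at -0.31 ± 0.09 and Col6a1 at -0.23 ± 0.07. With median scaling their median was -0.01 against 0.06 for all genes, and camera still placed them lower but at no unadjusted p under 0.05. Mmp13 fell by 0.59 ± 0.12 (adjusted p = 0.00817) and the lipoprotein lipase gene Lpl by 0.81 ± 0.18 (adjusted p = 0.0207). Tnfsf11 (-0.004 ± 0.13, adjusted p = 0.991), Tnfrsf11b (0.15 ± 0.08, adjusted p = 0.382) and Alpl (-0.06 ± 0.17, adjusted p = 0.901) did not pass. The shift of the oestrogen response list did not pass (5 of 13 positive, 0 past over all genes, 0 when adjusted over the list alone, median -0.04, camera adjusted p = 0.824). Only 13 of its 26 members were tested. Among those not tested were the receptor genes Esr1, Esr2 and Gper1 and the oestrogen-responsive genes Greb1 and Pgr, so the list is a weak check of E2 action.

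The number of genes called between E2 and vehicle moved with the processing and with the arrays used. With limma without an intensity trend 0 passed (1229 at an unadjusted p under 0.05; Fos adjusted p = 0.182, Myl2 0.123), and with median scaling 163 were higher and 38 lower. Leaving out either vehicle array left 20 genes each, leaving out E2 replicate 1 or 2 left 59 and 58, and leaving out dox replicate 1 or 2, arrays of neither group, gave 234 and 227. The 5 genes with the largest rise all lost their calls without either vehicle array, without E2 replicate 2 and without either dox plus E2 array (adjusted p 0.0576 to 0.412), and 4 of them without E2 replicate 1 or 3. These 5 genes also lost their calls with no background correction, the authors' scaled values, no detection filter and the replicate block (adjusted p 0.0505 to 0.158). So did H3c7, Mbip and Rasgrp3 with the stricter filter and Mindy3 with the mean of probes. Kif11 and Cdc20 lost theirs with median scaling, no detection filter, the mean of probes and the replicate block, and Kif11 also with the stricter filter. Lpl lost its call with no detection filter and the block, and Mmp13 with the mean of probes. With arrays left out, Kif11 lost its call in each of the cases named for the 5 genes (adjusted p 0.0512 to 0.316), Cdc20 in all but E2 replicate 3 (0.0507 to 0.289), Mmp13 without vehicle replicate 1 (0.241), Lpl without vehicle replicate 1 (0.383) or E2 replicate 3 (0.0603), and the collagen list without vehicle replicate 2 (0.0813) or E2 replicate 1 (0.13).

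**Figure D3:**
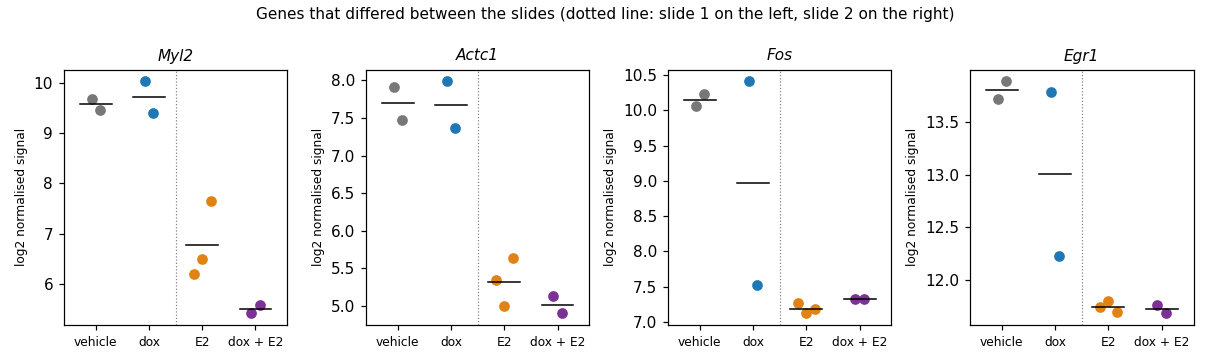
Normalised log2 intensity of Myl2, Actc1, Fos and Egr1 on each of the 9 arrays, by group, with a dotted line between the arrays of slide 1 (vehicle, dox) and slide 2 (E2, dox plus E2). Myl2 lies between 9.41 and 10.04 on slide 1 and between 5.41 and 7.65 on slide 2, and Fos in dox replicate 2 (7.52) lies far below the other slide 1 arrays.

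Dox plus E2 against dox gave the same contrast of slides in cells with dox. Among the genes with the largest fall were again heart and slow muscle genes: Myl2 at least 16.4-fold (adjusted p = 1.07e-09), Myl3 10.9-fold (-3.45 ± 0.27 on the log2 scale, n = 2 and 2, adjusted p = 1.69e-08), the myoglobin gene Mb at least 6.62-fold (adjusted p = 9.87e-08) and Actc1 at least 3.95-fold (adjusted p = 8.91e-07). The 13 tested heart muscle genes beyond those that prompted the class had a median of -0.43, and 0 of them passed. Egr2 fell 4.42-fold (-2.15 ± 0.27, adjusted p = 4.17e-05) and Lpl by 1.21 ± 0.19 (adjusted p = 0.00139). The 2 genes that rose were the transcription factor gene Glis1 (0.79 ± 0.15, adjusted p = 0.0178) and Dio3, a deiodinase that inactivates thyroid hormone (0.49 ± 0.10, adjusted p = 0.0291). In all 20 genes fell, and 1029 had an unadjusted p under 0.05. Of the 79 and 20 genes lower in the E2 comparisons 14 were shared (0.166 expected for independent lists, one-sided exact hypergeometric p = 8.5e-26), and of the 59 and 2 higher genes 0 were. Both comparisons set slide 2 against slide 1, so a difference between slides enters both, and both use the same spread estimate per gene.

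The skeletal and smooth muscle list shifted down (8 of 10 negative, median -0.17, camera adjusted p = 0.0115, and adjusted p = 0.531 with an estimated correlation). Its members past the threshold, 2 over all genes and 2 when adjusted over the list alone, were Actc1 and the troponin C gene Tnnc1 (-0.71 ± 0.14, adjusted p = 0.0232), both also expressed in heart. Collagen and matrix assembly genes (16 of 19 negative, median -0.09, camera adjusted p = 0.0282, and adjusted p = 0.611 with an estimated correlation; 0 past over all genes, 0 adjusted over the list alone) and integrated stress response genes (17 of 20 negative, median -0.10, camera adjusted p = 0.0115, and adjusted p = 0.611 with an estimated correlation; 0 past over all genes, 1 adjusted over the list alone) shifted down. With median scaling the medians of these lists were 0.07 and 0.05 against 0.12 for all genes, and camera still placed both lists lower but at no unadjusted p under 0.05. Cell cycle genes, which shifted down in E2 against vehicle and in dox against vehicle, did not pass here (10 positive and 14 negative, median -0.08, camera adjusted p = 0.681). Those other comparisons share the vehicle arrays. In dox plus E2 against dox, Tnfsf11 was at -0.27 ± 0.14 (adjusted p = 0.499) and Tnfrsf11b at 0.14 ± 0.09 (adjusted p = 0.607). With median scaling 273 genes were higher and 26 lower, against 2 and 20; without dox replicate 1 or dox plus E2 replicate 3, 10 genes passed, without dox plus E2 replicate 2, 14, without dox replicate 2, 74, and without E2 replicate 1, 38. Glis1, Dio3 and Tnnc1 lost their calls with no detection filter, without the intensity trend and with the replicate block, and Lpl lost its call with the latter 2. Egr2 lost its call without the trend. With arrays left out, Glis1, Dio3 and Tnnc1 lost them without dox replicate 1 or either dox plus E2 array (adjusted p 0.125 to 0.381), Dio3 also without either vehicle array (0.0556 and 0.052), Lpl without dox replicate 1 (0.0798) or dox plus E2 replicate 2 (0.117), the muscle list without dox plus E2 replicate 3 (0.0744), the collagen list without dox replicate 1 or either dox plus E2 array (0.0709 to 0.185), and the stress list without dox replicate 1 (0.147) or dox plus E2 replicate 3 (0.0799).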

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

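The comparison described here was fixed before the data were examined, and no test in this part was chosen after the result was seen. It sets the dox effect on slide 2, with E2, against that on slide 1, without E2. A dox effect that differs between slides cannot be told apart from an effect of E2. Of the 18 lists fixed then, 1 passed: the dox effect on inflammatory cytokine and NF-kB genes differed between cells with and without E2 in the test of the difference itself, with a median difference of 0.281 over 9 genes and 8 positive (limma camera adjusted p = 0.048, 0.0199 to 0.529 over the alternatives, 0.529 with an estimated correlation, and 0.0514 to 0.247 without any of 7 arrays in turn, that is all but E2 replicate 1 and dox plus E2 replicate 2).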

How the results depend on the processing

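No alternative here was chosen after a result was seen. Of 787 values of called genes under the alternatives 620 passed again, 167 kept the direction without passing, 0 reversed, and 9 values of other named genes newly passed. The cause of the following moves was not tested unless given. Median scaling called 5 genes for dox against vehicle (3 higher and 2 lower, against 3 and 0), 201 for E2 against vehicle (163 and 38, against 59 and 79; 97 of the 138 were kept) and 299 for dox plus E2 against dox (273 and 26, against 2 and 20; 18 of 22 kept), where it moves the median of all genes from -0.002 to 0.123, so changes under that setting are relative to a shifted median. For E2 against vehicle, 68 genes passed with no detection filter, which tests more dim genes, 91 with the mean of probes, 401 with array weights and 0 without the intensity trend (1229 at an unadjusted p under 0.05). Without the trend 3 genes passed for dox plus E2 against E2, 6 for dox plus E2 against dox and 7 for dox against no-dox arrays, and with the mean of probes 1 for dox against vehicle. The alternative with an estimated correlation, which changes more than the correlation, left 0 of 11 list shifts. Changes of dim genes shrank without background correction, for example H3c7 in E2 against vehicle from 0.995 to 0.38.

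Leaving out each array in turn, which can leave a group with a lone array assumed to vary like the others, gave 1 to 11 genes for dox against vehicle (11 without dox replicate 1), 2 to 9 for dox plus E2 against E2, 0 to 4 for the difference, 20 to 234 for E2 against vehicle, 10 to 74 for dox plus E2 against dox, 7 to 15 for dox against no-dox arrays and 8 to 13 list shifts. The size of the dox effect with E2 minus without stayed between 0.036 and 0.236. With the replicate block 69 genes passed for E2 against vehicle, 12 for dox plus E2 against dox and 7 for dox against no-dox arrays, and 3, 5 and 0 for the other comparisons. Same-numbered arrays correlated between -0.1 and 0.025 in their deviations from group means, which gives no sign of pairing by replicate number. In groups of 2 arrays these deviations mirror each other, so the check is weak, and whether the numbers pair the samples is not known. Signal over background limits genes near the detection floor, where only a bound can be given, and Runx2, Esr1, Pgr, Greb1 and Ibsp could not be read.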

Other observations

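The heart muscle and immediate early lists and their tests were chosen only after those genes were seen to differ, as were the comparison with other splits of the arrays and the use of median-scaled values for the tests of probe intensity. Beyond the genes already named, heart muscle genes on slide 2 included Csrp3, a protein of the muscle Z-disc (fell by 1.30 ± 0.26 in E2 against vehicle, adjusted p = 0.01), mitochondrial creatine kinase Ckmt2 (fell by 1.17 ± 0.27, adjusted p = 0.0312) and the muscle form of a cytochrome c oxidase subunit, Cox6a2 (fell by 0.57 ± 0.11, adjusted p = 0.00695). Among immediate early genes, Arc (fell by 1.32 ± 0.27, adjusted p = 0.0104), Jun (fell by 0.54 ± 0.10, adjusted p = 0.00669) and the phosphatase gene Dusp1 (fell by 0.44 ± 0.09, adjusted p = 0.00959) were lower, while the growth arrest gene Gadd45b was higher (0.49 ± 0.09, adjusted p = 0.00585). These values carry slide and E2 together.

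Within slide 2 the 9 heart muscle genes that prompted the list also had lower values with dox, though 0 of them passed with all arrays. In dox plus E2 against E2, 9 of 9 were negative (median -0.51, lowest Myl2 at -1.29, adjusted p = 0.0531); 0 passed with all arrays, 2 without E2 replicate 1 and 1 without E2 replicate 2 or either dox array, and the median was -0.36 without E2 replicate 3. The difference of dox effects was negative for 9 of 9 as well (median -0.59, 0 passed, -0.32 without dox replicate 1 and -0.93 without dox replicate 2). The 10 immediate early genes that prompted theirs had a median difference of 0.31 (9 positive, 0 passed), which was 0.69 without dox replicate 1 (3 passed) and -0.02 without dox replicate 2. Both sets were chosen from comparisons that share these arrays, so these values are no independent test. The 13 further heart and 18 further immediate early genes had medians of -0.034 each in dox plus E2 against E2 and of -0.086 and 0.020 in the difference, where either sign changed with single arrays left out.

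Few markers of macrophages, osteoclasts, endothelium and adipocytes could be tested. Of 20 macrophage and osteoclast markers 5 could be tested, of 12 endothelial markers 5 and of 16 adipocyte markers 5, and these lists passed in no comparison, though the adipocyte marker Lpl fell in both E2 comparisons. For dox against vehicle and dox plus E2 against E2, the camera adjusted p was 0.722 and 0.96 for RANKL shedding and vesicle sorting genes, 0.824 and 0.824 for the Wnt pathway, 0.675 and 0.824 for the BMP and TGF-beta pathway, and 0.733 and 0.961 for the interferon response. Chondrocyte markers (0.691 and 0.827) and matrix proteases and inhibitors (0.96 and 0.757) did not pass either. In these dox comparisons 0 members of the lists in this paragraph passed over all genes, and 1, a matrix protease list member with E2 present, did when adjusted over the list alone.

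Heart and slow muscle genes were lower on slide 2: the 9 that prompted this list had array means of 8.04 and 7.97 (vehicle), 8.43 and 7.95 (dox), 6.24, 6.32 and 6.87 (E2) and 6.00 and 5.83 (dox plus E2), with medians of -1.53 in E2 against vehicle (6 fell) and -1.84 in dox plus E2 against dox (9 fell). A slide effect on probes of that intensity is argued against: on median-scaled values, where these 9 genes had a median of -1.51, genes within 100 ranks of the same mean intensity had one of 0.071 and random lists of them lay between -0.136 and 0.25, above the -0.5 that such an effect would need (an upper bound of 0.25 was set at first, which these lists reached and which left the test open, and was dropped after the values were seen, as only a fall bears on this). A share of heart muscle cells or their RNA that differs between preparations stays open. Of 30 further heart markers 13 were tested (4 of the 30 and 1 of the 13 on earlier lists). Their median in E2 against vehicle was -0.255 (9 negative, 3 fell), between the -0.5 and -0.25 set beforehand as bounds. Matched random lists lay between -0.188 and 0.162. With the authors' scaled values, which have no background correction, the 13 had a median of -0.092, and that of the 9 prompting genes shrank too, to -0.633. In dox plus E2 against dox the 13 had a median of -0.43 (0 passed). The bright probes among them, Fhl2 (level 11.36 on vehicle replicate 1) and Cox6a2 (9.56), had 0.04 and -0.57 in E2 against vehicle. The 5 tested of 22 fast skeletal muscle genes (5 of the 22 and 2 of those tested on earlier lists) had a median of -0.081, inside the range of matched lists (-0.337 to 0.266). Their array means with vehicle were 5.78 and 5.82, near background, so they had little room to fall and form no firm contrast to heart muscle genes. An effect of E2 and a difference between slides or preparations cannot be told apart, because 0 slides hold arrays with and without E2.

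Immediate early genes were lower on slide 2 as well: the 10 that prompted this list had array means of 10.06 and 10.13 (vehicle), 10.18 and 9.26 (dox), and 8.62 to 8.75 on slide 2, with medians of -1.21 in E2 against vehicle (10 fell) and -0.73 in dox plus E2 against dox (5 fell). A slide effect on probes of that intensity is argued against in the same way: on median-scaled values these 10 genes had a median of -1.15, against 0.056 in genes within 100 ranks, with random lists between -0.067 and 0.181. A shared immediate early programme, as handling or a change of medium before lysis might evoke, stays open. In E2 against vehicle, 18 tested of 32 further members (2 of them on earlier lists) had a median of -0.214, between the -0.25 and -0.1 set beforehand. Of these 18, 14 were negative, 5 fell and 1 rose, and matched random lists lay between -0.115 and 0.077. With median scaling the 18 had a median of -0.08, against 0.056 for all genes. In dox plus E2 against dox their median was -0.192 (0 passed). Dox replicate 2, on slide 1 without E2, had low Fos (7.52) while its Myl2 level (9.41) stayed with the other slide 1 arrays, though a lone array excludes nothing. An effect of E2 cannot be told apart from slide here either, since 0 slides hold both.

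The genes of the dox response may reflect RUNX2, and each technical account was weighed in turn. Position on the slide follows dox. Within the 4 groups these 11 genes moved by 0.024 per position (SD 0.094) in the direction of the dox effect. That lay below the bound of 0.255 set beforehand. The test cannot decide, however: with a mean dox effect of 1.019 over 4.2 positions, a step under that bound could give all of it. Arrays of a group also lay at neighbouring positions, so a jump between the positions without and with dox would not be seen. Position stays open. Of 60 relabellings of these arrays, not of cultures, within slides, 1, the real one, gave 11 genes, and the highest other gave 5. Of 99 splits of the arrays into 4 and 5 (100 drawn, of which 1 could not be fitted), 2 gave as many genes, the real split with 11 included. The highest other split set dox replicate 2, E2 replicate 1 and both dox plus E2 arrays against the rest. It gave 42 genes, which points to a structure of the samples whose source is not known. Of the 42, 0 were immediate early genes, and the heart muscle gene Myl2 was among them (-0.959). Within slides the real grouping gave the most genes, but a split that did not follow dox gave more, so the count does not exclude chance. An effect of doxycycline on mitochondria stays open: the integrated stress response list had 13 of 20 positive and a median of 0.027 without E2, with the lower camera p of 0.219, and 8 of 20 positive and a median of -0.015 with E2, but the prediction set beforehand, a rise in neither, named no size, and medians this near 0 over members that go both ways decide nothing. No array had dox without the transgene, so doxycycline itself and RUNX2 cannot be told apart in these data.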
